A study of Oryza sativa with 9 samples.

How the data were processed

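RNA of rice seed was sequenced from 9 libraries, 3 each labelled CK, NaCl and MT100, sampled 22 hours after sowing. Libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols. The labels speak of replicates without saying whether these came from separate seed lots, so p-values measure only the spread between these samples, which may be technical. The authors deposited one table of FPKM per gene and library, with gene coordinates, gene lengths, symbols and descriptions, and its unit was taken from the table's name and values. Bowtie 0.12.2, Cuffdiff and the IRGSP-1.0 build are named in the submitters' processing notes. The role of each tool, the version of Cuffdiff, the counter, the annotation release and the use of strand are not given in the sources used here. Antisense and overlapping genes and close paralogs, such as histone, peroxidase and chitinase genes, may therefore share fragments, and their values are uncertain to that extent. The supplied table of RefSeq gene names did not match the identifiers and was not used, so names and coordinates are those of the deposited table.

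Each FPKM multiplied by its gene length was a whole multiple of a step fixed per library, so whole fragments could be recovered. All values (100%) came out whole within a tolerance of 0.02 fragments. The library size implied by each step was 0.951 to 1.05 times the recovered total. Totals ran from 7460787 to 11778429 fragments, highest in CK and lowest in NaCl. Counts of few fragments carry counting error besides the spread between libraries, so fragments are given for some genes near 0. Other values near 0 carry the same error where no fragments are given. Between replicates of a group, chi-square per degree of freedom was 8.30 to 24.1, far above sampling noise, and no libraries were merged.

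Values were analysed as log2(FPKM + 1), and fold changes are on that scale, which understates the change of genes at low levels. Of 105072 rows, the 22136 with an FPKM of at least 1 in at least 3 of the 9 libraries were tested. A fit of all 9 libraries with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trended prior variance) gave 3 comparisons, NaCl with CK, MT100 with NaCl and MT100 with CK. P-values are two-sided from limma's moderated test, adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Error on a log2 fold change is its standard error, and error on an FPKM is the SD of 3 libraries.

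Before the data were examined, 40 gene lists were written as patterns on symbols and descriptions. After the table was seen, 7 patterns were narrowed because they hit evident non-members: metallothioneins and thionins (methionine enzymes), osmolytes (a peptidase), class III peroxidases (a regulator), ribosomal proteins (organelle ribosomes), seed proteases (ubiquitin proteases), fermentation (unrelated enzymes) and heat shock proteins (histidine kinases). The 36 lists with at least 3 tested members were compared with all other genes by camera with a preset correlation of 0.01, adjusted over the lists of each comparison. Camera with an estimated correlation and fry were run beside it. Subsets of lists, such as DnaJ proteins or protein phosphatases 2C, were counted after the values were seen.

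Genes were named by a rule set before the data were examined. Per comparison it took the 8 genes with the largest rise and the 8 with the largest fall among those that passed the test, had groups that did not overlap, a mean of at least 5 FPKM in the higher group, and a symbol or informative description. It added up to 4 members with the lowest p for each list described, and the member with the highest mean of 11 fixed gene families of starch, hormone, catalase and melatonin metabolism. No row matched gibberellin 3-oxidase or tryptophan decarboxylase, and these are not reported here. Not all genes the rule selects are named in the text.

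The movement of salt-responsive genes in MT100 was measured as the share whose MT100 mean lay on the CK side of the NaCl mean, and as the median of (MT100 - NaCl)/(CK - NaCl) on the log2 scale. Since NaCl libraries enter both sides, the values were set beside 100 simulations in which MT100 equalled NaCl and genes were called anew, and beside a cross-fit with genes chosen without the NaCl library that served as the base. The covariance of fold changes that share the CK or the NaCl libraries was set beside 100 simulations of unchanged groups.

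The gene test was tested on simulated data with 200 changed genes per comparison. For NaCl with CK (21311 genes) it recovered 7.46% of 67 genes changed 1.5-fold, 40.3% of 67 changed 2-fold and 77.3% of 66 changed 4-fold, with 9 false calls. For MT100 with NaCl (21340 genes) it recovered 13.4% of 67, 49.3% of 67 and 77.3% of 66, with 2 false calls. For MT100 with CK (21331 genes) it recovered 4.48% of 67, 40.3% of 67 and 78.8% of 66, with 2 false calls. None was called in the wrong direction. The part recovered after Benjamini-Hochberg adjustment depends on how many genes change. These rates therefore hold for few changed genes and not for a comparison in which many changed. A list shifted by 0.5 in log2 was called in each comparison, an unchanged list in none, and all 945648 simulated fragment values were recovered. Noise was drawn independently per gene there, whereas the ribosomal protein list had an estimated correlation of 0.52. The simulation therefore cannot show how camera's preset correlation serves lists whose members vary together.

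Alternatives set before the data were examined were pseudocounts of 0.1 and 0.01, no filter, a filter at 5 FPKM, median-ratio scaling, quantile normalization, fits of the 2 groups compared, the replicate number as a block, a constant prior variance, robust empirical Bayes, array weights, an adjusted p of 0.01, a log2 fold change of at least 1, and leaving out each library. Chosen after seeing the data were voom on recovered fragments, fragments thinned to the shallowest library, protein-coding rows alone, at least 10 fragments in 3 libraries, and a cross-fit that also left out a CK library.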

Results

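The series held 9 RNA sequencing libraries of rice (Oryza sativa) seed, each sampled 22 hours after sowing. Seeds fell into 3 groups of 3 replicates, labelled CK, NaCl (salt) and MT100. The title of the series speaks of exogenous melatonin, a tryptophan-derived indoleamine, and of germination under salinity. CK, a usual abbreviation for a control, is taken here as the untreated group and MT100 as the group given melatonin; the labels used here give neither the unit behind its number nor whether salt was present. Whole fragments recovered from the FPKM (fragments per kilobase of gene length, scaled to library size) gave library totals of 10418572, 11325569 and 11778429 for CK, 8250240, 7460787 and 8620724 for NaCl, and 9115412, 9134643 and 9156623 for MT100. The gene table had 105072 rows, of which 22136 passed the expression filter, namely 14051 protein-coding genes, 5403 loci that the table itself numbers as new and 2682 other non-coding rows.

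The NaCl libraries separated from the others along the leading principal component, which held 47.8% of the variance of log2(FPKM + 1). The NaCl libraries lay at 86.3, 62.6 and 68.0, the CK libraries at -40.2, -47.2 and -47.0, and the MT100 libraries at -17.1, -23.4 and -42.1. Storage protein transcripts, a mark of the endosperm, took 1.17% ± 0.411 (SD, n = 3) of fragments in CK, 1.29% ± 0.346 in NaCl and 1.08% ± 0.237 in MT100. These shares overlapped between the 3 groups. Ribosomal protein transcripts took 4.74% ± 0.624 in CK, 3.41% ± 0.289 in NaCl and 4.85% ± 0.226 in MT100.

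**Figure D1:**
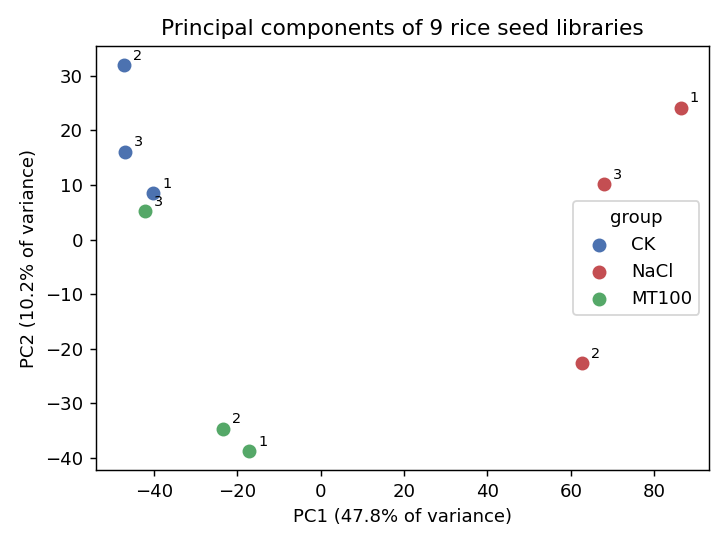
Principal components of log2(FPKM + 1) over 22136 rows, with PC1 (47.8% of variance) on the horizontal axis and PC2 (10.2%) on the vertical axis; each point is a library, coloured by group and numbered by replicate. The 3 NaCl libraries lie at 62.6 or above on PC1, and the CK and MT100 libraries lie below -17.

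The comparison of NaCl with CK asked how salt altered the transcriptome of germinating seed. Most of the DNA replication and histone genes tested were lower in salt. Many genes for peroxidases of the cell wall, phenylpropanoid enzymes, ribosomal proteins, light-harvesting proteins and jasmonate were lower too. Among genes of late seed maturation, protein phosphatases 2C and DnaJ chaperones, more were higher than lower. In all, 6570 of 22136 genes passed the test, 2762 of them higher and 3808 lower in NaCl. Under quantile normalization 3372 were higher and 3225 lower, so the excess of falls depended on the normalization. At least 2-fold changes numbered 765 upward and 1865 downward on the log2(FPKM + 1) scale.

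A mitotic kinase gene and a syntaxin gene were among the largest falls. CDKB2-1 (OS08G0512600, chromosome 8, 25419884 to 25421722, build IRGSP-1.0 as for all positions here), a cyclin-dependent kinase that acts at the onset of mitosis, fell from 148 ± 2.12 FPKM (SD, n = 3) in CK to 4.01 ± 0.878 in NaCl, a log2 fold change of -4.90 ± 0.15 (SE, adjusted p = 5.9e-06). The syntaxin gene OS03G0736500, described as KNOLLE-related and thus of the family that builds the cell plate at cytokinesis (chromosome 3, 30192888 to 30194132), fell from 138 ± 27.0 to 0.971 ± 0.722 FPKM, with only 2 to 15 fragments per NaCl library. For the list of DNA replication and histone genes, of the 61 members tested, 1 was higher and 40 lower (1 and 45 when adjusted over the list alone); camera adjusted p = 1.48e-12, and adjusted p = 0.417 with an estimated correlation. The histone H4 genes OS04G0583600 and OS05G0462700 changed by -3.81 ± 0.22 and -3.76 ± 0.24 in log2, and the H2B genes OS08G0490900 and H2B.9 (OS05G0574300) by -4.28 ± 0.28 and -2.36 ± 0.14. All 4 genes of the MCM replicative helicase that were tested were lower. The ribosomal protein list moved by less but as broadly: of the 117 members tested, 1 was higher and 77 lower (1 and 84 when adjusted over the list alone), with a mean log2 fold change of -0.49 (camera adjusted p = 5.81e-12, and adjusted p = 0.417 with an estimated correlation). Its members with the lowest p were the 60S acidic protein P3 gene OS06G0701400 (-0.71 ± 0.10), OS03G0297100 for S7 (-0.97 ± 0.15), OS05G0477300 for S26 (-0.83 ± 0.14) and OS01G0304000 for L29 (-0.97 ± 0.17).

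Class III peroxidases and phenylpropanoid genes were more often lower than higher in salt. The list of expansins and xyloglucan hydrolases was not called (8 higher and 15 lower of 41, camera adjusted p = 0.232). CSLD4 (OS12G0555600), a cellulose synthase-like protein, fell from 59.5 ± 11.1 to 0.522 ± 0.471 FPKM, and the CASP-like gene OS11G0649600 from 65.9 ± 11.1 to 1.08 ± 1.01. The cortical cell delineating protein gene OS03G0103100 went from 73.3 ± 41.9 to 0.924 ± 0.747 FPKM. BURP2 (OS05G0217800) measured 36.6 ± 23.8 FPKM in CK, and its NaCl libraries held 0 or 1 fragment each. Of the class III peroxidases, which cross-link wall polymers with hydrogen peroxide, 66 genes were tested, of which 3 were higher and 38 lower (5 and 39 when adjusted over the list alone); camera adjusted p = 8.62e-10, and adjusted p = 0.417 with an estimated correlation. OS10G0109300 measured 22.9 ± 8.58 FPKM in CK against 0.183 ± 0.244, OS01G0205900 87.5 ± 6.46 against 32.0 ± 0.578, and OS01G0543100 23.8 ± 5.26 against 6.17 ± 0.242; OS03G0368900 measured 8.23 ± 1.78 in CK and had no fragment in any NaCl library. In the phenylpropanoid list, which holds enzymes of lignin and flavonoid synthesis, of the 33 members tested, 2 were higher and 15 lower (2 and 19 when adjusted over the list alone; camera adjusted p = 7.16e-05, and adjusted p = 0.417 with an estimated correlation). CAD8A (OS09G0399800) fell from 42.6 ± 6.99 to 1.59 ± 0.460 FPKM, CAD2 (OS02G0187800) from 119 ± 10.1 to 19.5 ± 5.94, and CAD6 (OS04G0229100) and the chalcone isomerase-family gene OS11G0116300 fell by 2.24 and 1.77 on the log2 scale. CAD3 (OS10G0430200), annotated like them as a cinnamyl alcohol dehydrogenase, rose from 1.14 ± 0.107 to 18.3 ± 12.2 FPKM.

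The lists of jasmonate, pathogenesis-related and antioxidant genes were called lower as well. Those of auxin response, cytokinin, brassinosteroid, ethylene and gibberellin signalling were not called (camera adjusted p from 0.0981 to 0.608). LOX1.1 (OS03G0738600, chromosome 3, 30315456 to 30318959), a 9-lipoxygenase of linoleate, fell from 1284 ± 468 to 27.4 ± 14.2 FPKM (log2 fold change -5.60 ± 0.42, SE, adjusted p = 8.69e-05). It belonged by name to the jasmonate list, although jasmonate is made through another class of lipoxygenases. In that list, of the 27 members tested, 0 were higher and 12 lower (0 and 13 when adjusted over the list alone; camera adjusted p = 0.0233, and adjusted p = 0.417 with an estimated correlation). The repressor gene TIFY10C (OS09G0439200) changed by -1.57 ± 0.28, and the allene oxide synthase CYP74A2 (OS03G0225900) was near the detection floor in NaCl, with at most 3 fragments per library; CYP74A4 (OS02G0218800) had none there. Among pathogenesis-related genes, of the 26 members tested, 1 was higher and 17 lower (1 and 18 when adjusted over the list alone; camera adjusted p = 6.41e-05, and adjusted p = 0.417 with an estimated correlation). The chitinase genes OS07G0500300, CHT10 (OS01G0287600) and CHT9 (OS05G0399400) changed by -1.99 ± 0.16, -1.80 ± 0.30 and -2.84 ± 0.51, and the glucanase gene OS03G0669300 by -0.83 ± 0.14. Of antioxidant enzymes, 29 members were tested, of which 3 were higher and 13 lower (4 and 15 when adjusted over the list alone; camera adjusted p = 0.0162, and adjusted p = 0.417 with an estimated correlation). The cytosolic ascorbate peroxidase APX2 (OS07G0694700) fell from 712 ± 37.4 to 275 ± 12.4 FPKM and the Cu-Zn superoxide dismutase SODCC1 (OS03G0351500) from 250.1 ± 10.3 to 104 ± 8.07. BAS1 (OS02G0537700), a peroxiredoxin, and APX6 (OS12G0178100) changed by -1.07 ± 0.10 and -0.78 ± 0.10. CATB (OS06G0727200), the catalase with the highest level, measured 258 ± 32.6 in CK and 321 ± 37.9 in NaCl (adjusted p = 0.0931). In the list of metallothioneins and thionins, of the 14 members tested, 1 was higher and 8 lower (2 and 9 when adjusted over the list alone; camera adjusted p = 0.0162, and adjusted p = 0.417 with an estimated correlation), among them a thionin-domain locus on chromosome 6 (18467001 to 18468118) that fell from 60.5 ± 8.15 to 1.05 ± 0.175 FPKM and MT4C (OS12G0571100), which fell from 27.5 ± 17.8 to 1.06 ± 0.526. In the photosynthesis list, of the 29 members tested, 0 were higher and 18 lower (1 and 22 when adjusted over the list alone; camera adjusted p = 1.5e-06, and adjusted p = 0.417 with an estimated correlation). The light-harvesting gene OS11G0242800 measured 25.8 ± 14.0 FPKM in CK and 2.58 ± 0.468 in NaCl, and the oxygen-evolving protein gene OS07G0544800 33.6 ± 15.4 and 3.57 ± 1.20.

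The LEA and abscisic acid signalling lists were called higher, each with a minority of its members called. Those of storage proteins and abscisic acid synthesis were not called (camera adjusted p = 0.313 and 0.918). EMP1 (OS05G0349800, chromosome 5, 16518577 to 16519493), a late embryogenesis abundant (LEA) protein of the dry embryo, rose from 131 ± 64.6 FPKM to 2050.3 ± 1203 (log2 fold change 3.89 ± 0.52, SE, adjusted p = 0.00126). The LEA and dehydrin list had 15 members tested, 4 higher and 1 lower (4 and 1 when adjusted over the list alone; camera adjusted p = 0.0246, and adjusted p = 0.497 with an estimated correlation). Its call ended without CK replicate 1 or NaCl replicate 1, and that of the jasmonate list without NaCl replicate 1. Metallothioneins and thionins lost their call with the filter at 5 FPKM (adjusted p = 0.0791). OS03G0168100 stood at 184 ± 73.7 in CK and 601 ± 301 in NaCl and lost its call without CK replicate 3, and the dehydrin gene OS03G0655400 went the other way, from 458 ± 49.7 to 306 ± 33.7, with its call lost without CK replicate 2, NaCl replicate 1 or NaCl replicate 3. In the abscisic acid signalling list, of the 49 members tested, 15 were higher and 5 lower (18 and 7 when adjusted over the list alone; camera adjusted p = 0.0172, and adjusted p = 0.417 with an estimated correlation). Protein phosphatases 2C, a family whose clade A dampens abscisic acid signalling, made up 42 of these members, and 11 of the 42 were higher and 5 lower. Their clades were not examined, so the list call is not read as a change of abscisic acid signalling. OS05G0572700 (phosphatase 2C 51) changed by 1.50 ± 0.19 and OS01G0656200 (phosphatase 2C 8) by 2.09 ± 0.39, while OS07G0507000 (phosphatase 2C 62) fell from 67.2 ± 9.57 to 38.2 ± 1.83 FPKM. Of heat shock proteins and their co-chaperones, 100 members were tested, of which 32 were higher and 8 lower (35 and 8 when adjusted over the list alone; camera adjusted p = 1.18e-05, and adjusted p = 0.417 with an estimated correlation). DnaJ proteins made up 38 of them, 14 higher and 1 lower, whereas 2 of 11 small heat shock proteins were higher and 3 lower. The DnaJ genes OS02G0693200, OS03G0648400 and DJA6 (OS04G0549600) changed by 0.94 ± 0.08, 1.08 ± 0.12 and 0.80 ± 0.09, and OS03G0831000 by -2.85 ± 0.24.

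Other strong rises were in ETR4 (OS07G0259100), an ethylene receptor, from 1.26 ± 0.666 to 13.8 ± 8.19 FPKM, and in the cysteine protease gene OS07G0480900, described as RD19D, from 186 ± 16.4 to 1151 ± 814. A pectinesterase locus on chromosome 4 (27706669 to 27708862) rose from 12.8 ± 1.26 to 76.1 ± 35.5, and the hexosyltransferase gene OS07G0687900 from 7.05 ± 0.677 to 57.3 ± 54.4. The translocator protein homolog OS05G0151200 and ENODL1 (OS01G0748150) changed by 2.46 ± 0.63 and 2.44 ± 0.59, calls that were lost without CK replicate 3 and without CK replicate 2, respectively. AMY1.1 (OS02G0765600), the alpha-amylase with the highest level and an enzyme of starch breakdown in the endosperm, measured 9863 ± 1441 FPKM in CK and 5363 ± 975 in NaCl (adjusted p = 0.0106), a call that was lost under quantile normalization and with no filter. SNAT1 (OS05G0481000), which acetylates serotonin, measured 9.06 ± 1.09 and 6.45 ± 0.686 FPKM (adjusted p = 0.041), and its call was lost under quantile normalization and when CK replicate 1 or 3, any NaCl replicate, or MT100 replicate 2 or 3 was left out. ASMT1 (OS09G0344500) measured 0.941 ± 0.822 and 1.11 ± 0.379 (adjusted p = 0.722). NCED4 (OS07G0154100), of abscisic acid synthesis, measured 0.315 ± 0.320 and 1.40 ± 0.239 FPKM (adjusted p = 0.0235), a call that was lost without CK replicate 2 or CK replicate 3. The abscisic acid 8'-hydroxylase CYP707A7 (OS09G0457100) measured 1.20 ± 0.221 and 0.559 ± 0.551 (adjusted p = 0.134), the gibberellin 20-oxidase gene OS03G0856700 149 ± 27.6 and 187 ± 37.6 (adjusted p = 0.192), and the gibberellin 2-oxidase gene OS01G0757200 4.51 ± 1.46 and 2.87 ± 1.41 (adjusted p = 0.198).

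The test was limma's moderated test with Benjamini-Hochberg adjustment over 22136 genes. None of the 36 gene lists tested was called by camera with an estimated correlation, and fry, which asks whether a list moves one way without comparing it with other genes, called 24. The directions of all 12 lists called were kept under median-ratio scaling and under quantile normalization.

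**Figure D2:**
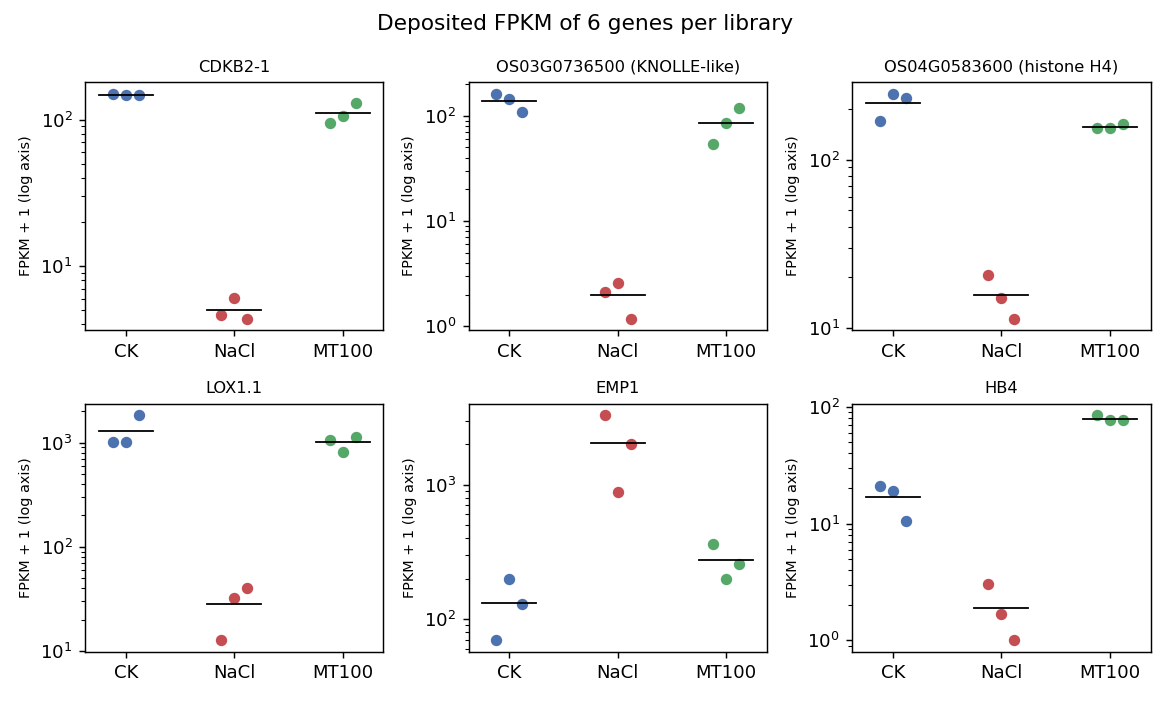
FPKM + 1 on a log axis for CDKB2-1, OS03G0736500 (KNOLLE-related), OS04G0583600 (histone H4), LOX1.1, EMP1 and HB4 in CK, NaCl and MT100; points are libraries (n = 3 per group) and lines are group means. For CDKB2-1 the means were 148, 4.01 and 109.6 FPKM in CK, NaCl and MT100, and for EMP1 131, 2050.3 and 272.

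The comparison of MT100 with NaCl asked which transcripts differed between the melatonin group and the salt group. The 12 gene lists called in NaCl against CK were called here as well by camera with its preset correlation, each in the opposite direction. With an estimated correlation 0 of 36 lists were called in either comparison. Both comparisons use the same 3 NaCl libraries, which favours opposite directions even without a change in MT100. Across genes the fold changes of the 2 comparisons had a covariance of -0.493, against -0.0577 in 100 simulations of unchanged groups, and a correlation of -0.874, against -0.502. The simulations also set NaCl equal to CK, so these correlations are not comparable. Among replication, ribosomal, peroxidase, phenylpropanoid, jasmonate and light-harvesting genes more were higher than lower in MT100. Among LEA and heat shock genes, and in the abscisic acid signalling list, which is mostly protein phosphatases 2C, more were lower. In all, 4693 of 22136 genes passed the test, 2768 higher and 1925 lower in MT100.

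For DNA replication and histone genes, of the 61 members tested, 33 were higher and 1 lower (40 and 1 when adjusted over the list alone; camera adjusted p = 3e-13, and adjusted p = 0.468 with an estimated correlation). CDKB2-1 (OS08G0512600) stood at 109.6 ± 18.1 FPKM (SD, n = 3) in MT100, and the KNOLLE-related gene OS03G0736500 at 84.9 ± 32.8, a log2 fold change over NaCl of 5.45 ± 0.35 (SE, adjusted p = 7.41e-05). The histone genes OS04G0583600, OS05G0462700 and H2B.9 (OS05G0574300) were higher by 3.36 ± 0.22, 3.22 ± 0.24 and 1.89 ± 0.14 in log2, and the H2A variant gene OS10G0418000 by 1.94 ± 0.15. In the ribosomal protein list, of the 117 members tested, 63 were higher and 2 lower (82 and 2 when adjusted over the list alone; camera adjusted p = 1.09e-12, and adjusted p = 0.468 with an estimated correlation), led by OS06G0701400 (P3, 0.64 ± 0.10), OS03G0297100 (S7, 0.91 ± 0.15), OS05G0477300 (S26, 0.79 ± 0.14) and OS08G0117300 (S13-2, 0.74 ± 0.13).

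LOX1.1 (OS03G0738600) measured 1002 ± 164 FPKM in MT100 (log2 fold change 5.29 ± 0.42, SE, adjusted p = 0.000163), and in the jasmonate list, of the 27 members tested, 9 were higher and 0 lower (9 and 1 when adjusted over the list alone; camera adjusted p = 0.0238, and adjusted p = 0.468 with an estimated correlation). TIFY10C (OS09G0439200) and the lipoxygenase CM-LOX1 (OS08G0508800) were higher by 1.95 ± 0.28 and 2.08 ± 0.32, and CYP74A2 (OS03G0225900) rose from 0.102 ± 0.0623 to 3.80 ± 0.886 FPKM. CSLD4 (OS12G0555600) stood at 38.8 ± 12.3 FPKM, and BURP2 (OS05G0217800) at 30.1 ± 19.9. Of class III peroxidases, 66 genes were tested, of which 29 were higher and 3 lower (33 and 3 when adjusted over the list alone; camera adjusted p = 3.33e-08, and adjusted p = 0.468 with an estimated correlation). OS05G0134800 measured 31.6 ± 11.1 FPKM where NaCl libraries held at most 3 fragments, OS01G0543100 and OS01G0205900 were higher by 1.70 ± 0.16 and 1.07 ± 0.11, and OS07G0694300 (peroxidase 21) by 0.97 ± 0.10. In the phenylpropanoid list, of the 33 members tested, 11 were higher and 2 lower (13 and 2 when adjusted over the list alone; camera adjusted p = 0.00501, and adjusted p = 0.468 with an estimated correlation). CAD8A (OS09G0399800), CAD2 (OS02G0187800) and CAD6 (OS04G0229100) were higher by 3.22 ± 0.19, 2.07 ± 0.24 and 1.72 ± 0.25, and CAD3 (OS10G0430200) changed by -2.80 ± 0.38.

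Of antioxidant enzymes, 29 members were tested, of which 12 were higher and 3 lower (12 and 5 when adjusted over the list alone; camera adjusted p = 0.018, and adjusted p = 0.468 with an estimated correlation). APX2 (OS07G0694700) rose to 609 ± 68.8 FPKM, the chloroplast superoxide dismutase SODCP (OS08G0561700) from 30.1 ± 2.91 to 68.9 ± 12.3, and the peroxiredoxins PRXIIC (OS01G0675100) and BAS1 (OS02G0537700) by 1.20 ± 0.15 and 0.85 ± 0.10 in log2. In the photosynthesis list, of the 29 members tested, 14 were higher and 2 lower (17 and 2 when adjusted over the list alone; camera adjusted p = 1.77e-05, and adjusted p = 0.468 with an estimated correlation). The light-harvesting gene OS07G0562700 went from 12.9 ± 2.31 to 60.9 ± 9.38 FPKM, the oxygen-evolving protein gene OS07G0544800 from 3.57 ± 1.20 to 26.0 ± 4.64, and the photosystem I genes OS03G0778100 and OS08G0560900 changed by 2.11 ± 0.31 and 2.99 ± 0.44. Among pathogenesis-related genes, of the 26 members tested, 5 were higher and 1 lower (5 and 1 when adjusted over the list alone; camera adjusted p = 0.0426, and adjusted p = 0.585 with an estimated correlation). OS07G0500300, CHT12 (OS03G0418000) and CHT9 (OS05G0399400) were higher by 1.67 ± 0.16, 2.30 ± 0.32 and 3.09 ± 0.51, and the chitinase gene OS08G0518900 was lower, at 108 ± 14.9 FPKM against 212 ± 21.7. In the list of metallothioneins and thionins, of the 14 members tested, 5 were higher and 1 lower (7 and 1 when adjusted over the list alone; camera adjusted p = 0.0426, and adjusted p = 0.468 with an estimated correlation), with MT2C (OS05G0111300) at 1778 ± 163 FPKM in NaCl and 3050.3 ± 660.4 in MT100. The jasmonate list lost its call without NaCl replicate 1 and with no filter (adjusted p = 0.0719). Pathogenesis-related genes lost theirs without NaCl replicate 1 or 2 or MT100 replicate 3. They also lost it with no filter (0.0609), with filters at 5 FPKM (0.0868) and at 10 fragments (0.0523), with array weights (0.137) and by voom (0.0531). Metallothioneins and thionins lost theirs without NaCl replicate 2 or 3. They also lost it with the replicate block (0.0516), with a fit of the 2 groups alone (0.1), with array weights (0.0502), with filters at 5 FPKM (0.214) and at 10 fragments (0.0523) and by voom (0.0674).

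On the lower side, EMP1 (OS05G0349800) measured 272 ± 83.5 FPKM in MT100 (log2 fold change -2.76 ± 0.52, SE, adjusted p = 0.00778). In the LEA and dehydrin list, of the 15 members tested, 0 were higher and 3 lower (0 and 3 when adjusted over the list alone; camera adjusted p = 0.0144, and adjusted p = 0.535 with an estimated correlation), with OS03G0168100 at 155 ± 49.5 FPKM. Of heat shock proteins, 100 members were tested, of which 6 were higher and 32 lower (9 and 45 when adjusted over the list alone; camera adjusted p = 1.62e-07, and adjusted p = 0.347 with an estimated correlation). HSP17.9A (OS03G0266300) fell from 702 ± 217 to 135 ± 59.1 FPKM, the DnaJ genes OS02G0693200 and DJA6 (OS04G0549600) changed by -0.94 ± 0.08 and -0.69 ± 0.09, and OS03G0831000 by 2.18 ± 0.24. By family, DnaJ proteins had 1 higher and 13 lower of 38, and small heat shock proteins, to which HSP17.9A belongs, 3 higher and 2 lower of 11. In the abscisic acid signalling list, of the 49 members tested, 2 were higher and 8 lower (2 and 10 when adjusted over the list alone; camera adjusted p = 0.0299, and adjusted p = 0.468 with an estimated correlation), a list call that ended without NaCl replicate 1 or NaCl replicate 3 and with the filter at 5 FPKM. OS05G0572700 (phosphatase 2C 51) and the transcription factor gene OS01G0867300 (ABA responsive element binding factor 1) changed by -1.44 ± 0.19 and -0.96 ± 0.13. OS04G0659500 (phosphatase 2C 45) changed by -0.39 ± 0.10, and its call was lost without any 1 of the NaCl replicates 1 and 3 or of the 3 MT100 replicates. INO1 (OS03G0192700), which makes inositol phosphate for phytate, fell from 306 ± 110.0 to 44.1 ± 10.2 FPKM, OS11G0149200 from 327 ± 167 to 61.3 ± 22.0, ETR4 (OS07G0259100) to 1.42 ± 0.870 and the RD19D gene OS07G0480900 to 219 ± 73.9. OS05G0151200 measured 38.1 ± 20.1 in MT100 (adjusted p = 0.041), a call lost when any library other than NaCl replicate 2 or MT100 replicate 3 was left out.

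HB4 (OS03G0234100, chromosome 3, 7100048 to 7101570), a non-symbiotic haemoglobin, and a pair of neighbouring genes for cortical cell delineating proteins on chromosome 10 were higher in MT100 than in NaCl, with means above those of CK. HB4 measured 15.9 ± 5.50 FPKM in CK, 0.907 ± 1.05 in NaCl and 78.4 ± 4.55 in MT100 (MT100 against NaCl, log2 fold change 5.53 ± 0.39, adjusted p = 0.000116; MT100 against CK, adjusted p = 0.133). OS10G0349400 measured 28.6 ± 9.76, 1.11 ± 1.91 and 105 ± 3.54 FPKM in the same order, and OS10G0349300 31.4 ± 10.2, 3.07 ± 3.13 and 115 ± 16.4. AMY1.1 (OS02G0765600) measured 7047 ± 1502 FPKM in MT100 (adjusted p = 0.189 against NaCl). SNAT1 (OS05G0481000) measured 8.92 ± 0.914 (adjusted p = 0.0603), NCED4 (OS07G0154100) 0.438 ± 0.268 (adjusted p = 0.0554) and CATB (OS06G0727200) 256 ± 21.2 (adjusted p = 0.106). The count of 4693 genes fell to 3019 without NaCl replicate 1 and to 2972 without MT100 replicate 3.

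The salt-responsive genes were then followed into MT100. Of the 3808 genes lower in NaCl than in CK, 2445 were higher in MT100 than in NaCl, where independent lists of these sizes would share 476. Of the 2762 genes higher in NaCl, 1577 were lower in MT100, where independent lists would share 240.2. Only 1 gene passed both tests in the same direction. The NaCl libraries stood on both sides of these overlaps, so part of the excess may come from them. Over all 6570 salt-responsive genes, 99.0% had an MT100 mean on the CK side of the NaCl mean. In 100 simulations in which MT100 equalled NaCl and genes were called anew, the share was 56.8% to 59.2%. They called 8248 to 8582 genes and drew noise independently per gene, so this range leaves out the spread of genes that vary together. Single NaCl libraries set against the mean of the other NaCl libraries gave 31.8%, 64.9% and 53.4%. The share was 96.1% when genes were chosen without the NaCl library that served as the base. The median gene had moved 0.804 of the way from NaCl to CK, and 0.801 with that left-out base. The 3 MT100 libraries gave 0.746, 0.757 and 0.905. Each CK library, set against the mean of the other CK libraries, gave 0.915, 1.02 and 1.06.

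**Figure D3:**
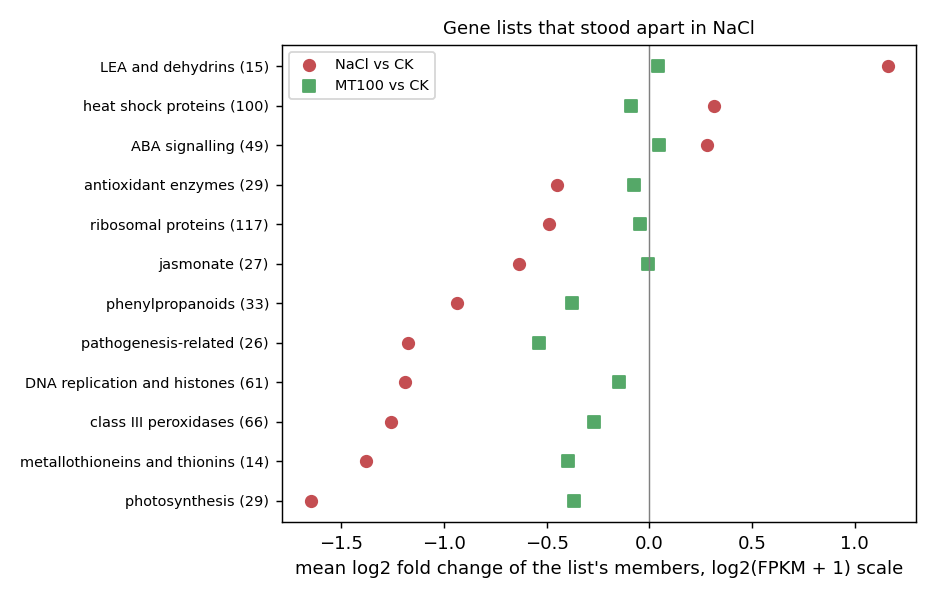
Mean log2 fold change on the log2(FPKM + 1) scale (horizontal axis) of the 12 gene lists called in NaCl against CK (vertical axis, number of members tested in parentheses); circles are NaCl against CK and squares MT100 against CK. The squares lie closer to 0 than the circles for each list: DNA replication and histones had -1.19 in NaCl and -0.15 in MT100, and LEA and dehydrins 1.16 and 0.04.

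The comparison of MT100 with CK asked what separated the melatonin group from CK. Few genes passed the test. Of 22136 genes, 6 passed, 2 higher and 4 lower in MT100, and 1935 had an unadjusted p under 0.05. For 3279 genes (14.8%) the groups did not overlap, where 10% would by order alone. In simulated data the test found 4.48% of 1.5-fold and 40.3% of 2-fold changes here. The few calls therefore do not show that few genes differed. A globin-domain locus on chromosome 3 (7096670 to 7097750, plus strand), just upstream of HB4, measured 4.69 ± 1.33 FPKM in CK, 0.569 ± 0.316 in NaCl and 22.4 ± 3.81 in MT100 (log2 fold change over CK 2.05 ± 0.23, SE, adjusted p = 0.0456). OS09G0571200, a protein-coding gene with no described function (chromosome 9, 22806006 to 22806996), measured 17.1 ± 5.97, 0.289 ± 0.135 and 0.918 ± 0.689 (adjusted p = 0.0284). A locus on chromosome 2 (23044549 to 23045308) measured 10.6 ± 0.915, 1.89 ± 0.0482 and 3.60 ± 0.781 (adjusted p = 0.0456). The other 3 were short non-coding rows of 20, 47 and 58 bases whose libraries held at most 3 fragments. The globin locus was named by the rule set beforehand, and the other 5 were chosen after their values were seen. None of the 3 named loci kept its call when any CK replicate was left out.

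By gene list, camera called 5, all lower in MT100 than in CK, although none of their members passed the test over all genes. These were pathogenesis-related genes (mean log2 fold change -0.54, 5 of 26 lower when adjusted over the list alone, camera adjusted p = 0.000229, and adjusted p = 0.561 with an estimated correlation), phenylpropanoids (-0.38, 3 of 33 lower and 1 higher, camera adjusted p = 0.00121, and adjusted p = 0.561 with an estimated correlation), class III peroxidases (-0.27, 10 of 66 lower and 3 higher, camera adjusted p = 0.00996, and adjusted p = 0.653 with an estimated correlation), photosynthesis (-0.37, 0 of 29 lower, camera adjusted p = 0.0121, and adjusted p = 0.746 with an estimated correlation) and NAC transcription factors (-0.29, 1 of 15 lower, camera adjusted p = 0.0187, and adjusted p = 0.561 with an estimated correlation). The chitinase gene OS08G0518900 measured 227 ± 37.5 FPKM (SD, n = 3) in CK and 108 ± 14.9 in MT100 (adjusted p = 0.0817), and the chitinase genes OS11G0701900 and OS11G0701400 45.2 ± 14.2 against 20.1 ± 2.88 and 231 ± 85.5 against 92.9 ± 28.5. CAD8A (OS09G0399800) measured 42.6 ± 6.99 and 23.2 ± 4.72 (adjusted p = 0.24), and CCR1 (OS02G0808800) 124 ± 25.6 and 66.5 ± 20.4 (adjusted p = 0.316). The peroxidase OS03G0368900 measured 8.23 ± 1.78 and 1.99 ± 0.880 (adjusted p = 0.0854), and peroxidase 21 (OS07G0694300) 18.8 ± 1.63 and 28.5 ± 1.79 (adjusted p = 0.136). The NAC gene OS11G0127600 measured 9.80 ± 3.05 and 4.14 ± 0.0299 (adjusted p = 0.21). Fry called none of the lists here. The call of the peroxidase list ended without CK replicate 1 or MT100 replicate 1, with no filter (adjusted p = 0.0509) and with the filter at 5 FPKM (0.223). That of the NAC list ended without CK replicate 2 or MT100 replicate 3, with no filter (0.0551) and at 5 FPKM (0.153). That of the photosynthesis list ended without CK replicate 1 or 2 or MT100 replicate 1 or 3, with a pseudocount of 0.01 (0.0597) and at 5 FPKM (0.192). AMY1.1 (OS02G0765600) was at adjusted p = 0.517.

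The 6 gene calls were sensitive to single libraries, to the filter, to the pseudocount and to the model. Pseudocounts of 0.1 and 0.01 called 4 and 6 genes, 0 of them among these 6. The replicate block and the fit of the 2 groups alone each kept 2 of the 6. No gene was called without CK replicate 1 (2082 at an unadjusted p under 0.05), 1 without CK replicate 2, and 2 each without CK replicate 3, NaCl replicate 1, MT100 replicate 1 or MT100 replicate 2. With the filter at 5 FPKM limma called 0 genes (1188 at an unadjusted p under 0.05), and voom on recovered fragments, chosen after seeing the data, called 27. Across genes, the covariance of the NaCl and MT100 fold changes over CK was 0.140, against 0.0570 in 100 simulations of unchanged groups sharing the CK libraries, a difference of 0.0831. The correlation was 0.455, against 0.498 in the simulations, and genes are not independent replicates. In the simulations NaCl equalled CK, whereas in the data it differed. These correlations are therefore not comparable, and 0.455 is not read as below expectation.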

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

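Voom, thinning, the protein-coding rows, the minimum of 10 fragments and the cross-fit over NaCl and CK libraries were chosen after seeing the data, and the other alternatives before. Of 4340 values of single genes under alternatives (186 results), 4213 kept their side of the threshold, 110 lost their call, 17 gained one and 0 reversed. A change of sign was counted as a reversal only where the gene was called in the main fit or in the alternative. Changes of sign in genes called in neither were not counted. For NaCl against CK, 6570 genes became 3163 at an adjusted p of 0.01 and 2630 with a log2 fold change of at least 1, both stricter by construction, and 4518 to 6446 with one library left out. For MT100 against NaCl, 4693 became 1857 and 1866 under the same thresholds, and 2972 to 4535 with one library left out, at 3019 without NaCl replicate 1 and 2972 without MT100 replicate 3. For MT100 against CK, 6 became 18 with no filter, 0 with a filter at 5 FPKM (limma, 1188 at an unadjusted p under 0.05), 15 with a constant prior variance, 3 with robust empirical Bayes, 15 with array weights, 2 at an adjusted p of 0.01, 27 by voom (2 shared with the 6), 12 with thinned fragments and 1 among protein-coding rows. Leaving out one library gave 0 to 8, with 0 without CK replicate 1 (2082 at an unadjusted p under 0.05), 1 without CK replicate 2, and 2 each without CK replicate 3, NaCl replicate 1, MT100 replicate 1 or MT100 replicate 2. Pseudocounts of 0.1 and 0.01 called 4 and 6 genes there, 0 of them shared with the 6. With at least 10 fragments, a smaller set, 6945 and 5193 genes were called for NaCl against CK and MT100 against NaCl. The stricter thresholds lower counts by construction; for the other changes the cause was not tested.

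Among gene lists, camera with an estimated correlation called 0 of 36 in each comparison, against 12, 12 and 5 with the preset correlation. Fry, which asks another question, called 24, 20 and 0. For MT100 against CK, a filter at 5 FPKM called 2 lists, and leaving out one library gave 3 (without MT100 replicate 1) to 9 (without CK replicate 3); the cause was not tested. Of salt-responsive genes, 99.0% lay on the CK side in MT100, 96.1% in the cross-fit over NaCl libraries, 95.7% in the cross-fit over NaCl and CK libraries, and 97.9% (without MT100 replicate 3) to 99.4% with one library left out. The cross-fits use single libraries as the base, which adds noise by construction. The median return of 0.804 ranged from 0.737 to 0.835 with one library left out. The covariance stayed above its simulated range under each alternative run. Replicate numbers are shared between groups by label only: correlations of same-numbered deviations ran from -0.123 to 0.0980, and 5 of 9 libraries correlated best with their own number. With the replicate block the counts were 5858, 4028 and 2 genes. For MT100 against CK the simulated test found 4.48% of 1.5-fold and 40.3% of 2-fold changes, so real changes of this size may be missed.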

Other observations

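Chosen only after the results were seen were the depth, cross-fit, unspliced-transcript and few-fragment tests, the fry test of departure from a shared axis, and the screen for genes outside both other groups; the other tests were set beforehand. Several gene lists that were not called by camera still held strongly changed members. For NaCl against CK, aquaporins had 0 higher and 5 lower of 16 (0 and 6 adjusted over the list alone; camera adjusted p = 0.0598), and the channel NIP1-1 (OS02G0232900) fell from 193 ± 25.9 FPKM (SD, n = 3) to 65.9 ± 9.36 and stood at 179 ± 24.3 in MT100. PIP1-2 (OS04G0559700) measured 37.7 ± 6.06, 15.4 ± 2.18 and 28.4 ± 6.73 FPKM in CK, NaCl and MT100. Oil-body genes had 3 higher and 0 lower of 4 (3 and 0 adjusted over the list alone; camera adjusted p = 0.113), expansins and xyloglucan hydrolases 8 higher and 15 lower of 41 (8 and 17 adjusted over the list alone; camera adjusted p = 0.232), and cytokinin genes 3 higher and 7 lower of 22 (4 and 9 adjusted over the list alone; camera adjusted p = 0.0981). The beta-amylase gene OS03G0351300, of starch breakdown, rose from 99.7 ± 16.3 to 257 ± 90.7 FPKM and fell to 72.2 ± 14.6 in MT100, while AMY1.4 (OS08G0473600) measured 514 ± 59.0, 688 ± 139.6 and 527 ± 88.0. Storage protein genes had 0 higher and 0 lower of 12 (0 and 0 adjusted over the list alone; camera adjusted p = 0.313).

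MT100 lay outside both other groups for 403 genes above and 344 below, that is 3 libraries beyond the other 6. Of these, 148 and 133 were also called against NaCl at a mean of at least 5 FPKM. With all 9 libraries alike, 1.19% of the 22136 rows tested would lie outside on each side by order alone. Since NaCl differed from CK, that share is not the one expected with MT100 equal to CK, which was not computed. The counts are therefore not read as a set of genes particular to MT100. Above lay HB4 (OS03G0234100), the actin-depolymerizing factors ADF9 (OS07G0484200) and ADF6 (OS04G0555700, 4.73 ± 0.520, 1.93 ± 0.255 and 13.5 ± 5.58 FPKM in CK, NaCl and MT100), and EXPA30 (OS10G0535900, 7.59 ± 3.18, 2.23 ± 1.23 and 25.3 ± 11.7). Below lay DREB1A (OS09G0522200, 13.4 ± 3.84, 37.2 ± 27.5 and 6.07 ± 0.557), TPP1 (OS02G0661100) and HSP24.1 (OS02G0758000, 104 ± 54.0, 114 ± 40.9 and 44.1 ± 8.75). Against CK none of these genes passed in limma, with adjusted p from 0.133 (HB4) to 0.616 (DREB1A).

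Salt-responsive genes in MT100 lay near CK. Lower depth of the NaCl libraries is argued against, since the median return was 0.801 with all libraries thinned to one depth and 0.804 ± 0.0885 (SD of 3 MT100 libraries) at full depth, and selection of genes on the same NaCl libraries is argued against by 0.834 in the cross-fit. A single shared axis from NaCl to CK, which germination progress might give, was tested on the 12 lists called. The test held no measure of germination stage, so a shared axis would not tell progress from another cause. Returns ran from 0.541 ± 0.317 for pathogenesis-related genes to 1.29 ± 0.181 for heat shock proteins. Of these lists, 3 lay beyond 2 of their SDs, which met the bound set beforehand for ruling a shared axis out. That bound is held here to be wrong, because an SD of 3 libraries over 12 lists leaves out the error of the CK and NaCl means, so a fry test was added after that result and called 0 of 12 lists (lowest adjusted p = 0.57; limma put 4 genes off the axis, 1675 at an unadjusted p under 0.05), and a shared axis cannot be told apart from list-specific returns. It may also be that MT100 seed had little or no salt, which the labels do not settle and no test here addresses.

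Loci numbered as new rose more often than coding genes in NaCl, 921 higher and 441 lower against 1694 higher and 3226 lower. Low expression is argued against by a difference of 39.7 percentage points in the share of higher calls between rows matched on mean level, and carry-over of genomic DNA by a median log2 fold change of 0.20 in the highest-expressed part of these loci. Of called loci outside coding genes, 66.5% ± 2.13 (binomial SE) were higher against 34.4% ± 0.677 of coding genes, a difference of 32.0 percentage points. The excess was thus not confined to loci inside coding genes. That difference restates the pattern and is no test of unspliced transcripts of known genes. By position these loci lie beyond the annotated bounds of coding genes, and transcripts that run past those bounds were not examined. For loci inside a coding gene on its strand the share was 91.7% ± 3.57 (55 higher and 5 lower). This was above that of loci outside by 25.2 percentage points (Fisher's exact test, p = 2.22e-05), which unspliced transcripts could give. Fisher's test and the binomial errors take loci as independent and do not measure the spread between libraries. No locus was compared with the gene around it, and the use of strand in counting is not known. Loci that overlap a coding gene without lying inside it on its strand had shares of 66.2% ± 1.73 on its strand and 71.2% ± 5.90 on the other, not called different from loci outside (Fisher's exact test, p = 0.951 and 0.558), which leaves the explanation open for them. It remains open whether these loci were defined from the same reads, which could favour loci high in a given group, and a salt response of their own was not tested.

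Of the 6 genes called in MT100 against CK, 3 were short rows with at most 3 fragments in any library, and voom on recovered fragments called 0 of these 3, consistent with few fragments. Of the other 3, voom called 2, the globin locus and OS09G0571200, which argues against few fragments as the whole cause for these. It did not call the chromosome 2 locus (voom adjusted p = 0.0595). A real effect of the treatment on the globin locus may be read from these values only as a hypothesis. None of the 6 calls survived the loss of any CK library, or a pseudocount of 0.1 or 0.01.

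Splits of the 6 libraries of each comparison into 3 against 3 number 10, too few to give a share under 0.05. The real split called 6570 genes for NaCl against CK and the highest other 3, so that 1 split reached the real count; for MT100 against NaCl it was 4693 and 2, with 1 split, and for MT100 against CK 6 and 7, with 2 splits. For gene lists the real split called 12 and the highest other 11 in NaCl against CK (1 split), 12 and 13 in MT100 against NaCl (2 splits), and 5 and 9 in MT100 against CK (3 splits).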
